A study of Danio rerio with 10 samples.

How the data were processed

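RNA from pools of whole zebrafish embryos was measured on 10 Affymetrix zebrafish arrays, 1 pool per array. Per the labels, the embryos came from a line in the AB/WIK background that carries the cz3 allele of earl grey (egy), were kept at 28 °C, and were sorted by morphology into mutants and normal-looking siblings. Siblings are called wild-type in the labels; a recessive defect leaves heterozygotes looking normal, so sibling pools may hold both genotypes. Each array received labelled cRNA made from 7 micrograms of total RNA.

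The deposited values are linear signal intensities, 1 per probe set and array. MAS5 made them, per the submitters' processing notes; its version, the scaling target and the detection calls are not given in the sources used here. The arrays' 2% trimmed means were 1500.4 on all 10 arrays and differed by a factor of at most 1.00004, so the authors had scaled the arrays to one trimmed mean, and the values were used as deposited. Scaling to one mean fixes the total signal, so a difference is relative to the rest of the array. A mismatch-corrected MAS5 signal near the background is noisy, and without detection calls the noise of low probe sets was held down by a filter and a pseudocount only.

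Of 15617 probe sets in the table, 115 controls were left out. Platform annotation dated 2016 gave 1 gene symbol to 10795 of the other 15502, several symbols to 135 and none to 4572, for 8793 genes. For 10711 probe sets the gene ID was also in a RefSeq gene table, through which 1 symbol was updated. Only probe sets with exactly 1 symbol are named, and a gene with several is shown by the probe set with the highest mean over all arrays. For the named genes no other probe set moved the opposite way. The files state no genome build, so no coordinates are given. No column of per-sample values was left without a sample.

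Signals were analysed as log2(signal + 65), where 65 is 10% of the overall median of 647.8, so a log2 difference understates the change of low probe sets. The lowest 25% by mean (3876 probe sets, limit at a signal of 223) was left out, which kept 11626 probe sets and 7280 genes. A limma model (version 3.58.1, R 4.3.3) with a mean for each of the 4 groups (sibling day 3, n = 2; mutant day 3, n = 2; sibling day 5, n = 3; mutant day 5, n = 3) was fitted to all arrays, with eBayes moderation along a mean-variance trend (6 residual and 6.58 prior degrees of freedom). The comparisons were mutant against sibling on day 3, on day 5 and averaged over both days, the difference between the days, and sibling day 5 against day 3. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Errors of log2 differences are standard errors from this model, and errors of signals are SDs between pools. The labels call the replicates biological, so p-values measure the spread between pools and not between embryos. The number of arrays limits the precision.

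28 gene lists with 1146 entries, of which 844 were on the array (29 through an older symbol or synonym), were fixed with the tests, the alternatives and the rule for named genes before the data were examined. They cover the spliceosome (4 lists: Sm and LSm ring, U4/U6.U5 tri-snRNP, U1 and U2 snRNP, PRP19 complex and catalytic steps), SR and hnRNP splicing regulators, p53 targets and apoptosis, DNA replication and S phase, G2 and mitosis, ribosomal proteins, nucleolus and ribosome biogenesis, proteasome, heat shock and unfolded protein response, and oxidative phosphorylation. The tissue lists are photoreceptors, lens, retinal and neural progenitors, differentiated neurons, cartilage and pharyngeal arches, thymus and lymphoid cells, myeloid cells, erythroid cells, exocrine and endocrine pancreas, liver, intestine, skeletal muscle, heart, pigment cells, and skin and keratins. Each list, and the union of the 4 spliceosome lists, was tested with camera from limma (preset correlation 0.01) in the day 3, day 5 and averaged comparisons, 87 tests in one Benjamini-Hochberg family, with 1 probe set per gene. The test was repeated with the correlation between genes estimated from the residuals. A study of these mutants is known to have reported coordinated changes of spliceosome components, so the spliceosome lists were not chosen blind to that theme.

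Named genes are sart3, the zebrafish orthologue of p110, and mdm2, and those with the largest changes past the threshold without overlap between mutant and sibling arrays of a day: 10 higher and 10 lower in the averaged and day 5 comparisons, 6 and 6 on day 3, and 8 and 8 between the sibling days. Where nothing passed, the 5 and 5 with the smallest raw p were taken. Each list gave up to 4 members past the threshold per direction. Genes with clone names only were skipped (1 on day 5, 2 between the sibling days). 1 further gene in the rule is not reported here, and cdkn1a was not analysed here.

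Groups were taken from the titles, and some labels conflict with them. The strain label of sibling replicate 2 on day 3 says mutant; it was kept as a sibling. The later time is day 5 (120 h) in titles and age labels but 4 days in the series design text, and the source names of sibling replicate 2 and mutant replicate 3 of that day say day 4; it is called day 5 here. The residuals of same-numbered mutant and sibling arrays, which the labels do not tie together, correlated on day 5 (r = 0.23, 0.26 and 0.22, across probe sets, which are not independent) and other pairs did not (−0.15 to −0.10), while on day 3 r was −0.05. Residuals are centred within each group, so the low values of the other pairs follow from the high ones and are no separate evidence. The numbers were taken to pair the arrays on day 5, from the data alone.

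Alternatives were quantile normalization, median centring, pseudocounts at 1% and 50% of the median (6 and 324), no filter, a filter on the lower 50%, eBayes without the trend, array weights, the replicate number as a block, each array left out, the 2 arrays with day 4 source names left out, sibling replicate 2 of day 3 counted as a mutant, fits to the arrays of one day or to the siblings only, and, for lists, the estimated correlation and other choices of probe set. Lists without either array of doubtful labels or levels, lists under other scalings, and list tests of the day difference were added after seeing the data. On simulated data for 11626 probe sets, with 50 changed per size, a log2 change of 1 was recovered for 76% on day 3, 84% on day 5 and 94% averaged, and one of 0.5 for 16%, 16% and 36%, with 6, 9 and 8 false calls. A list shifted by 0.5 was called in all 3 tests. The simulated noise was drawn independently for each gene, so this does not show how the list test behaves with correlated genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.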

Results

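Zebrafish earl grey embryos carry a recessive defect in the orthologue of human p110, a protein that helps to rebuild the U4/U6 snRNP after each round of splicing. The mutants have small heads and eyes, poorly developed pharyngeal arches and a small thymus. Gene expression was measured in pools of whole mutant embryos and of their normal-looking siblings, collected 3 days (2 pools of each) and 5 days (3 pools of each) after fertilization. The study set out to describe the defect at the level of transcripts. Median signals of the 10 arrays lay between 596 and 671, and Spearman correlations between arrays of a group lay between 0.958 and 0.983. The sibling pool on day 3 that one label calls mutant (replicate 2) correlated at 0.983 with the other day 3 sibling pool and at most at 0.970 with a mutant pool.

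sart3, the gene affected in these mutants, was lower in every mutant pool than in every sibling pool. On day 3 its signal was 2521 ± 6.5 (SD, n = 2) in siblings and 555 ± 132 (SD, n = 2) in mutants, and on day 5 it was 2131 ± 416 (SD, n = 3) and 349 ± 399 (SD, n = 3). The log2 difference was −2.82 ± 0.45 on day 5 (adjusted p = 1.3e-03) and −2.45 ± 0.36 over both days (adjusted p = 5.6e-04). On day 3 it was −2.08 ± 0.56 and missed the threshold (adjusted p = 0.083). That day 3 value passed without mutant replicate 1 of day 5 (adjusted p = 0.049) or without replicate 3 (adjusted p = 8.9e-05), which enter the shared estimate of spread, with the replicate number as a block (adjusted p = 0.029), with array weights (0.014) and with a pseudocount at 50% of the median (0.022). Mutant replicate 3 of day 5 had a signal of 809, against 105 and 132 in replicates 1 and 2, which lie under the filter limit of 223 and leave the size of the fall uncertain. The sibling pool with the conflicting label had 2516, as high as its partner. Where the sart3 probes lie relative to the mutation is not known from the files, so the signal checks the sorting of the pools only as far as the mutation lowers the transcript.

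**Figure D1:**
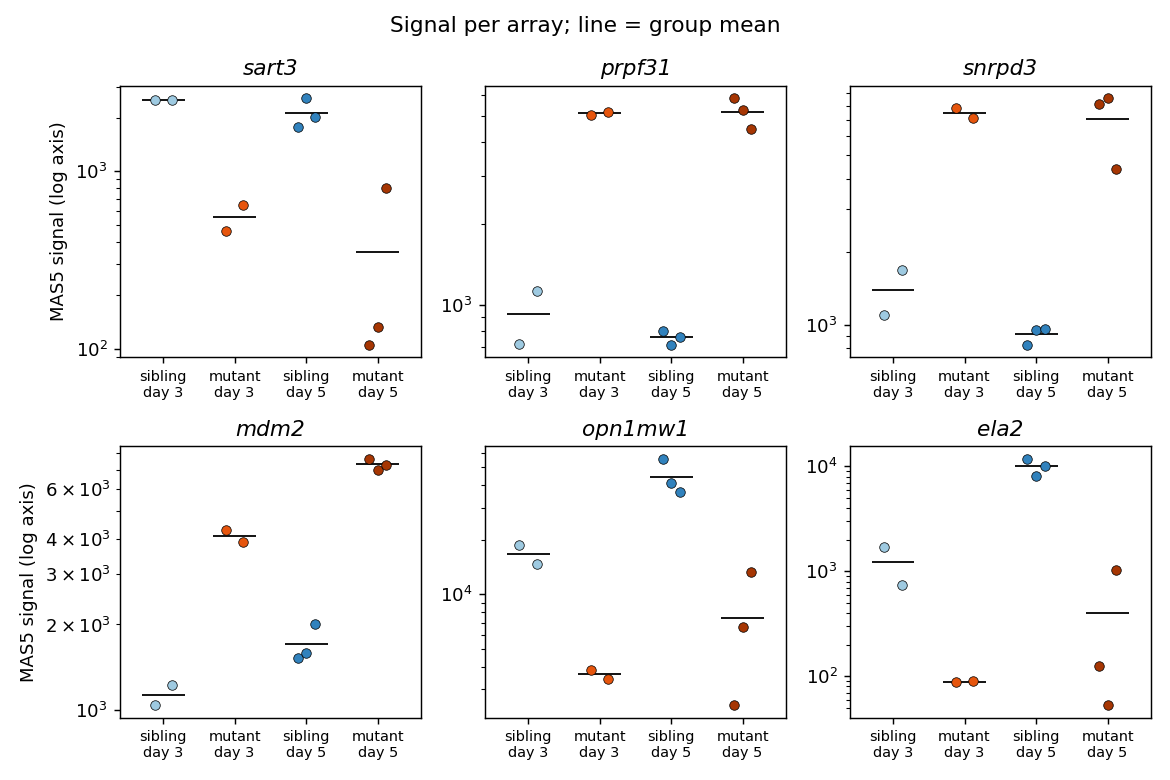
MAS5 signal (log axis) of 6 genes in each of the 10 pools, with a line at each group mean. In every panel the mutant and sibling pools of a day do not overlap: sart3, opn1mw1 and ela2 are lower in mutants, and prpf31, snrpd3 and mdm2 are higher.

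The first comparison asked which transcripts differ between mutants and siblings when both days are averaged. The core of the spliceosome rose: of 83 measured genes in the 4 spliceosome lists, 51 rose and none fell, and the median log2 difference was 0.45. Targets of p53 rose as well, led by mdm2, a ubiquitin ligase, at 1.93 ± 0.10. Digestive enzymes of the pancreas and genes of photoreceptors fell the most, with ela2, an elastase, at −4.03 ± 0.47 and the green cone opsin opn1mw1 at −2.52 ± 0.33. Of 11626 probe sets, 1906 passed the threshold, 808 higher and 1098 lower in mutants, which stand for 600 and 677 genes. More than 2-fold differences were seen for 103 higher and 130 lower probe sets. The split depends on the scaling: with each array centred on its median, 1081 were higher and 776 lower, so the share of higher calls went from 42.4% to 58.2%. The count was 970 without sibling replicate 1 of day 3, 1146 without sibling replicate 2 and 1253 without mutant replicate 2 of that day, and it was 548 with sibling replicate 2 of day 3 counted as a mutant, as one label has it.

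Within the spliceosome the rise was largest in the rings and the tri-snRNP. The Sm and LSm proteins, which encircle the snRNAs, had a median of 1.3, and 11 of 14 rose (12 adjusted over the list alone), among them snrpd3 (2.60 ± 0.17), lsm8 (2.42 ± 0.11) and lsm7 (2.33 ± 0.17). The U4/U6.U5 tri-snRNP had a median of 1.12, and 12 of 17 rose (13 rose and 1 fell adjusted over the list alone), with prpf31 at 2.54 ± 0.12, prpf3 at 2.44 ± 0.17 and eftud2 at 2.28 ± 0.11. In the U1 and U2 snRNPs 16 of 25 rose (20 adjusted over the list alone; median 0.55), including the U2 proteins sf3a2 (1.91 ± 0.12) and sf3b4 (1.67 ± 0.12). In the PRP19 complex and catalytic steps 12 of 27 rose (14 adjusted over the list alone; median 0.29), including isy1 (2.07 ± 0.23) and xab2 (1.58 ± 0.15). Adjusted over the list alone, 58 of the 83 rose and 1 fell. By camera the 83 genes stood higher than other genes with adjusted p = 3.8e-32. With an estimated correlation the tri-snRNP list held (adjusted p = 0.035), while the union and the U1 and U2 list had adjusted p = 0.0501 with an estimated correlation, and the Sm and LSm and PRP19 lists 0.092. The SR and hnRNP splicing regulators, which choose splice sites, did not pass as a list over both days (median 0.03, adjusted p = 0.11, and 0.042 without sibling replicate 2 of day 3). On day 3 they passed as higher (median 0.07, adjusted p = 6.7e-03), but not with an estimated correlation (0.28) or after quantile normalization (0.067). Of their 45 genes 7 rose and 3 fell over both days (8 and 3 adjusted over the list alone), with srsf11 at 0.74 ± 0.09 and srsf2a at 0.54 ± 0.07. Because a study of these mutants is known to have described the spliceosome genes, their count is not independent of that choice.

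Among the other genes with the largest rises, ice1 (3.03 ± 0.23), a component of the complex that promotes snRNA transcription, stood at 316 ± 119 (SD, n = 2) in day 3 siblings and 2948 ± 24.0 (SD, n = 2) in day 3 mutants. uspl1, a Cajal body SUMO protease, rose by 2.43 ± 0.14, bmb by 2.62 ± 0.22 and frg1, a protein found with the spliceosome, by 2.28 ± 0.14. Of 26 p53 targets and apoptosis genes 12 rose and none fell (12 rose and 1 fell adjusted over the list alone), with a median of 0.28 and adjusted p = 6.2e-09. This list held with an estimated correlation (adjusted p = 0.033). Its leading members after mdm2 were rps27l (1.80 ± 0.10), phlda3 (1.56 ± 0.11) and bbc3 (1.32 ± 0.12), the gene of the death-promoting protein Puma.

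The proteasome rose modestly, with a median of 0.22 and 13 of 32 genes up (18 adjusted over the list alone), for example psmd8 at 0.53 ± 0.08. Its list call had adjusted p = 7.7e-09, and adjusted p = 0.12 with an estimated correlation. Of 52 nucleolus and ribosome biogenesis genes 9 rose and 1 fell (13 and 2 adjusted over the list alone), with nolc1 at 0.63 ± 0.08 and nhp2 at 0.59 ± 0.07. That list held with an estimated correlation (adjusted p = 0.043). Of 34 heat shock and unfolded protein response genes 11 rose and none fell (the same counts adjusted over the list alone), while the list's median was 0.01. Those that rose include the stress factor atf3 (1.08 ± 0.19), the collagen chaperone serpinh1b (1.04 ± 0.11) and hsp90aa1.1 (0.87 ± 0.09). Its adjusted p was 0.025, 0.24 with an estimated correlation and 0.073 after quantile normalization. Skeletal muscle genes rose as a list, with a median of 0.23 and 15 of 36 up (21 adjusted over the list alone). casq2, a calcium store protein, rose by 0.62 ± 0.09, and hsp90aa1.1, which the muscle list shares with the heat shock list, led it. The muscle list had adjusted p = 4.0e-08, and adjusted p = 0.12 with an estimated correlation.

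Photoreceptor genes fell nearly as a whole: 24 of 27 were lower, 24 also adjusted over the list alone, with a median of −1.95. After opn1mw1 came gnat2 (−2.34 ± 0.28) and gngt2a (−2.20 ± 0.19), both parts of cone transducin, and rbp3 (−2.29 ± 0.19), which carries retinoids between cells. Of 14 genes on the exocrine and endocrine pancreas list 10 fell and 1 rose (11 and 3 adjusted over the list alone), with a median of −2.01. The insulin gene ins was the one that rose (0.38, limma adjusted p = 0.029), a call kept in 12 of 19 other settings. Trypsinogen prss1 (−3.02 ± 0.33), chymotrypsinogen ctrb.1 (−3.99 ± 0.58) and the lipase cel.1 (−3.34 ± 0.41) were among those that fell. Further digestive enzymes among the 10 largest falls were cela1.6 (−2.93 ± 0.29), ctrl (−2.74 ± 0.30), ela3l (−2.66 ± 0.28) and the carboxypeptidase cpa5 (−3.01 ± 0.37). The photoreceptor list had adjusted p = 6.4e-22, and 0.079 with an estimated correlation. The pancreas list had adjusted p = 1.4e-07, and 0.12 with an estimated correlation. Sizes are uncertain, here and below, where a group mean lies under the filter limit of 223. Among the genes named this holds in mutants for ela2, ela3l, fabp6 and amy2a on day 3, gngt2a and six6b on day 5 and cel.1 on both days, and in siblings for bmb on both days.

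Of 19 intestine genes 7 fell and none rose (9 fell adjusted over the list alone), with a median of −0.29. The bile acid binding protein fabp6 (−2.48 ± 0.30) and fabp2 (−1.50 ± 0.17) were among them. Their list call had adjusted p = 1.0e-03, and adjusted p = 0.17 with an estimated correlation. Genes on the neuron and progenitor lists fell too. Of 27 genes on the differentiated neuron list 18 fell (19 adjusted over the list alone), with a median of −0.44, adjusted p = 1.8e-13 and adjusted p = 0.033 with an estimated correlation. They include the myelin gene mbpa (−1.10 ± 0.12) and the neurogenic factor neurod1 (−1.08 ± 0.09). Of 33 retinal and neural progenitor genes 14 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of −0.30. Those that fell include the eye transcription factors vsx1 (−1.22 ± 0.14) and six6b (−0.96 ± 0.17). This list had adjusted p = 4.9e-05, and adjusted p = 0.095 with an estimated correlation.

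Small positive list shifts were called for erythroid cells (median 0.26, 3 of 14 rose and 1 fell, adjusted p = 0.012), skin and keratins (0.14, 6 of 28 rose and 4 fell, 0.015) and oxidative phosphorylation (0.12, 3 of 57 rose, 1.1e-04). Adjusted over the list alone, 5 rose and 1 fell in the erythroid list, 6 rose and 4 fell in the skin list, and none changed in oxidative phosphorylation. None of these 3 calls held with an estimated correlation (adjusted p = 0.19, 0.24 and 0.38), and the skin call also ended with quantile normalization (adjusted p = 0.055). In the skin list evplb, a cornified envelope protein, fell by 0.49 ± 0.08.

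The remaining lists did not pass over both days. On day 5 alone lens genes (median −0.18, adjusted p = 0.011) and ribosomal proteins (−0.11, 4.9e-03) passed as lower and heart genes (0.39, 0.048) as higher, none of them with an estimated correlation (0.27, 0.68 and 0.30). The heart call also ended with median centring (0.057) and, just over the threshold, without sibling replicate 2 of day 3. Of 43 DNA replication genes 3 rose (0 adjusted over the list alone; median −0.09, adjusted p = 0.77). Of 38 G2 and mitosis genes 5 fell, 5 also adjusted over the list alone, and the list's median (0.03), mean (−0.02) and test (lower, adjusted p = 0.88) differ in sign. Of 68 ribosomal protein genes 1 rose (0 adjusted over the list alone; median −0.05, adjusted p = 0.16), although the list passed as lower without sibling replicate 2 of day 3 (adjusted p = 0.042) and after quantile normalization (1.7e-06), while median centring turned its median to 0.01. Of 7 lens genes 2 fell, 2 also adjusted over the list alone (median −0.10, adjusted p = 0.12, and 0.0498 after quantile normalization), including the lens filament gene bfsp2 (−0.63 ± 0.12). Of 31 cartilage and pharyngeal arch genes 2 rose and 2 fell (0 and 2 adjusted over the list alone; median 0.08, adjusted p = 0.52), and the cartilage matrix gene matn1 fell by 0.85 ± 0.12.

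In the thymus and lymphoid list 3 of 7 genes fell, 3 also adjusted over the list alone (median −0.09, adjusted p = 0.053, 0.039 without mutant replicate 3 of day 5 and 0.0495 with median centring). In the myeloid list 2 of 17 fell, 2 also adjusted over the list alone, and its median (0.03), mean (−0.16) and test (lower, adjusted p = 0.87) differ in sign. One of these is cpa5, a digestive carboxypeptidase that fell with the pancreas enzymes, and the other is the granulin grna.1 (−0.57 ± 0.12). Of 27 liver genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; median −0.002, adjusted p = 0.59), and the sign of that median changed with the scaling. The fatty acid binding protein fabp10a (−2.36 ± 0.28) and urate oxidase, uox (−1.04 ± 0.12), fell. In the heart list 2 of 6 rose (2 adjusted over the list alone; median 0.24, adjusted p = 0.11), and in the pigment cell list 1 of 13 rose (1 adjusted over the list alone; median 0.13, adjusted p = 0.14), paics at 0.54 ± 0.09, an enzyme of purine synthesis. In all, 18 of 29 lists passed in the averaged comparison, 17 on day 3 and 21 on day 5, and 4, 5 and 4 held with an estimated correlation. A regrouping of the arrays within each day called as many as 20, against the 18 here. That regrouping keeps the real groups of day 5, and regroupings real on neither day called at most 17.

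**Figure D2:**
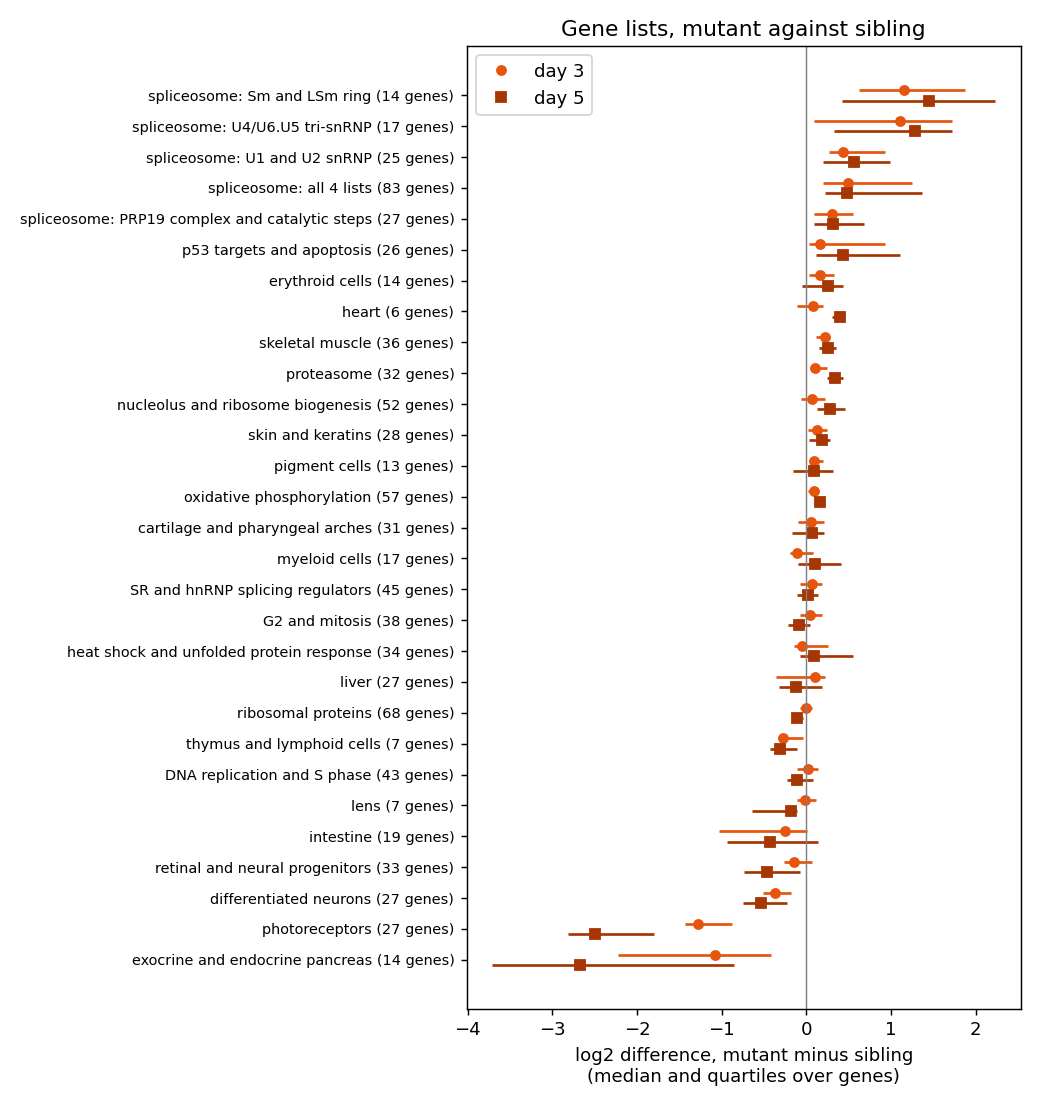
Median log2 difference between mutants and siblings for the 28 lists and the union of the spliceosome lists, on day 3 (circles) and day 5 (squares), with lines from the lower to the upper quartile over genes. Photoreceptors and pancreas lie lowest, at −1.28 and −1.08 on day 3 and −2.50 and −2.67 on day 5, and the Sm and LSm ring lies highest, at 1.15 and 1.44.

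On day 3, when the pools are youngest, the spliceosome had already risen: 33 of 83 genes rose and none fell (46 rose adjusted over the list alone), with a median of 0.49, adjusted p = 1.5e-38 and adjusted p = 0.043 with an estimated correlation. prpf31 rose by 2.42 ± 0.18, snrpd3 by 2.4 ± 0.27, prpf3 by 2.16 ± 0.26, ice1 by 3.02 ± 0.35 and frg1 by 2.25 ± 0.22. mdm2 rose by 1.80 ± 0.15, and 7 of 26 p53 and apoptosis genes rose (10 adjusted over the list alone). Of 27 photoreceptor genes 9 fell (21 adjusted over the list alone), with a median of −1.28, adjusted p = 2.1e-16 and adjusted p = 0.10 with an estimated correlation. Of 27 genes on the neuron list 5 fell (10 adjusted over the list alone), and of 14 pancreas genes 3 fell (8 fell and 1 rose adjusted over the list alone). matn1 fell by 1.32 ± 0.18.

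Of 11626 probe sets 238 passed on day 3, 137 higher and 101 lower in mutants; with median centring 155 were higher and 67 lower, so the share of higher calls went from 57.6% to 69.8%. With 2 pools per group this count leans on single pools: it was 48 without sibling replicate 1, 82 without sibling replicate 2 and 68 without mutant replicate 2 of day 3, and 400 without mutant replicate 3 of day 5. It was 505 with array weights. Counting sibling replicate 2 as a mutant leaves a lone sibling pool on day 3, and all day 3 calls were then lost. bmb rose by 2.22 ± 0.34, but lost its call without sibling replicate 1 (adjusted p = 0.084) or mutant replicate 2 of day 3 (0.064). The genes with the largest falls were less secure. gngt2a (−1.83 ± 0.30) and rbp3 (−1.72 ± 0.29) lost their calls without sibling replicate 1 (adjusted p = 0.11 and 0.13) or mutant replicate 2 (0.10 and 0.11). cel.1 (−2.96 ± 0.63, an uncertain size at a mean signal of 28.6 in mutants), prss1 (−2.42 ± 0.51), opn1mw1 (−2.18 ± 0.51) and the apolipoprotein gene apoda.2 (−1.95 ± 0.40) lost theirs without any one of the 4 day 3 pools, with adjusted p between 0.059 and 0.34. cel.1 also did without sibling replicate 1 or 2 of day 5 (0.051 and 0.054), prss1 without sibling replicate 1 (0.0501), and opn1mw1 without any sibling pool or mutant replicate 2 of day 5 (0.057 to 0.075).

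On day 5 digestive enzymes of the pancreas had the largest falls among the named genes. The signal of ela2 was 10042 ± 1870 (SD, n = 3) in siblings and 402 ± 542 (SD, n = 3) in mutants, a log2 difference of −5.10 ± 0.60. Mutant signals of 126 and 52.9 lie under the filter limit of 223, so the size of this fall is uncertain. cela1.6 (−4.01 ± 0.37), ela2l (−3.69 ± 0.34) and ctrb.1 (−4.44 ± 0.73) fell too, and 10 of 14 pancreas genes fell (10 fell and 2 rose adjusted over the list alone; median −2.67). Of 27 photoreceptor genes 23 fell (24 fell and 1 rose adjusted over the list alone; median −2.50), and rcvrn2, a recoverin, fell by 3.22 ± 0.25. The spliceosome genes were higher in mutants, with 46 of 83 up (54 adjusted over the list alone) and a median of 0.48, and lsm8 (2.74 ± 0.14), uspl1 (2.80 ± 0.18) and snrpg (2.30 ± 0.20) were among the 10 largest rises. The proteasome had 19 of 32 genes up (24 adjusted over the list alone) and the p53 list 13 of 26 (15 adjusted over the list alone). Of 33 retinal and neural progenitor genes 18 fell (20 fell and 1 rose adjusted over the list alone). With an estimated correlation the p53, neuron, nucleolus and tri-snRNP lists held (adjusted p = 0.033, 0.033, 0.035 and 0.036), and the union of spliceosome lists (0.070), photoreceptors (0.070), pancreas (0.10), proteasome (0.095) and progenitors (0.0501) had adjusted p above the threshold.

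Of 11626 probe sets 1690 passed on day 5, 752 higher and 938 lower in mutants. With median centring 961 were higher and 726 lower, so the share of higher calls went from 44.5% to 57.0%, and without sibling replicate 2 of day 5 the count was 1048. Of the 137 probe sets higher on day 3, 129 were also higher on day 5, where independent lists would share 8.86. Of the 101 lower on day 3, 90 were also lower on day 5, against 8.15. Both days share the same estimate of spread per probe set, so the calls are not independent and these chance values may be too low. All 238 had the same sign on both days, no probe set passed in opposite directions, and the log2 differences of the 2 days had r = 0.69 and rho = 0.53 across probe sets, which are not independent replicates.

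**Figure D3:**
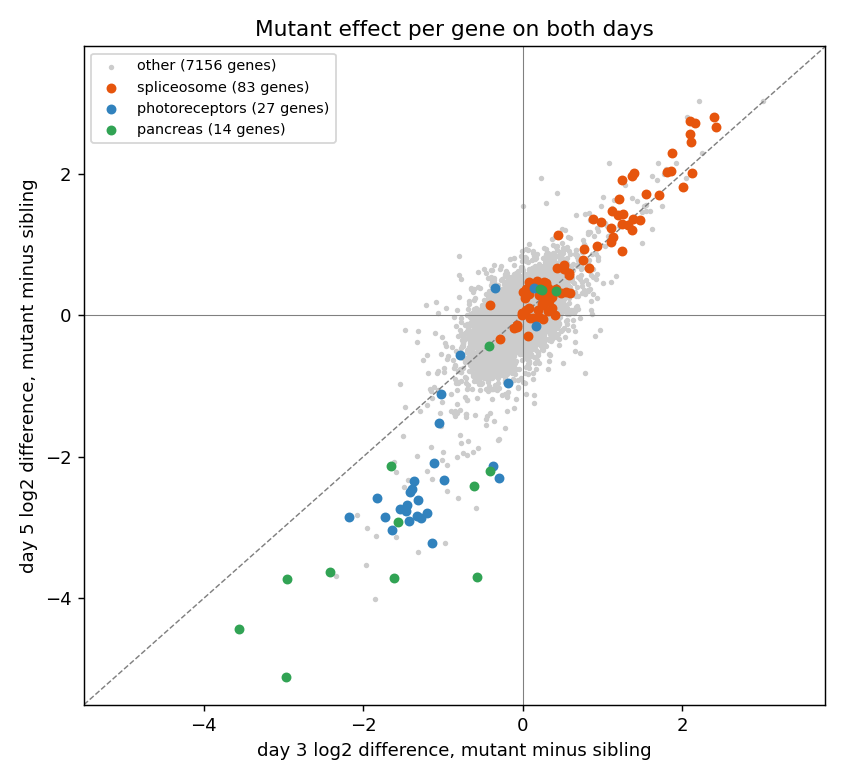
Log2 difference between mutants and siblings per gene on day 3 (horizontal axis) and day 5 (vertical axis), with spliceosome, photoreceptor and pancreas genes coloured and the dashed line marking equal differences. Spliceosome genes lie along the line, with medians of 0.49 and 0.48, while most photoreceptor and pancreas genes lie below it.

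Whether the mutant effect itself differed between the days was tested as the difference of both differences. No single gene passed. The genes with the smallest p among those moving upward from day 3 to day 5 were clu, the chaperone clusterin, with a log2 difference of 0.23 ± 0.19 on day 3 and 1.94 ± 0.16 on day 5 (adjusted p of the difference = 0.073), and socs3b, a feedback inhibitor of cytokine signalling, with 0.01 ± 0.19 and 1.54 ± 0.15 (0.090). In the other direction stood crx, the photoreceptor transcription factor, with −0.37 ± 0.19 and −2.12 ± 0.16 (0.073), the forebrain factor foxg1b with −0.77 ± 0.12 and −1.80 ± 0.10 (0.077), and the pancreas enzymes ela2l and amy2a (both 0.11). bcl7ba, dnd1, vmp1 and fabp1b.1, the other genes of the 5 and 5, had adjusted p between 0.16 and 0.26. By limma 0 of 11626 probe sets passed, and 772 had an unadjusted p under 0.05, where chance gives 581. With the replicate number as a block, a pairing taken from the day 5 data alone, 10 passed, 3 with a higher and 7 with a lower effect on day 5. In that fit crx had adjusted p = 8.6e-03, clu and amy2a 0.027, and socs3b and ela2l 0.033. The count was 8 with a pseudocount at 50% of the median, 6 with array weights and 26 without the 2 arrays with day 4 source names. Without mutant replicate 3 of day 5 the count was 50, with 6 higher and 44 lower, and clu (adjusted p = 5.5e-03), socs3b (8.9e-03), crx (0.014), foxg1b (0.014), ela2l (5.5e-03), amy2a (0.035) and fabp1b.1 (0.039) passed. Without mutant replicate 1 of day 3, or replicate 1 or 2 of day 5, 1 probe set passed, which was crx without replicate 2 (adjusted p = 3.5e-03).

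The last comparison described normal development, sibling pools on day 5 against day 3. The pancreas enzymes rose the most: 12 of 14 pancreas genes rose (13 adjusted over the list alone), with a median of 2.02, led by ctrl (3.21 ± 0.43), ela2l (3.14 ± 0.38), cela1.6 (3.13 ± 0.42) and ela3l (3.09 ± 0.40). Liver (12 of 27 up, 12 adjusted over the list alone) and intestine (9 of 19 up, 11 adjusted over the list alone, where 1 also fell) had no member that fell over all genes. The chitinase chia.2 rose by 2.97 ± 0.28, an uncertain size because its mean of 159 in day 3 siblings lies under the filter limit. Of 68 ribosomal protein genes 42 rose (60 adjusted over the list alone; median 0.38), and of 57 oxidative phosphorylation genes 27 rose and 2 fell (35 and 2 adjusted over the list alone). In the skin list 13 of 28 rose and 1 fell (19 and 3 adjusted over the list alone). Of the 83 spliceosome genes 2 rose and 23 fell (2 and 24 adjusted over the list alone; median −0.25), and of 45 SR and hnRNP genes 3 rose and 18 fell (5 and 21 adjusted over the list alone). These are counts of members, and no list test is reported here. The 3′ to 5′ ratio of the actin controls also differed between the sibling days (1.76 to 2.25, then 5.28 to 9.24), while that of the GAPDH controls moved the other way (1.70 to 1.87, then 1.27 to 1.41), and no test separates RNA quality from age in this comparison.

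cyp1a, a cytochrome P450 that responds to aryl hydrocarbons, fell the most (−3.53 ± 0.22), from a signal of 21075 ± 7894 (SD, n = 2) to 1709 ± 278 (SD, n = 3). Its relative cyp1c1 fell by 1.88 ± 0.36, though not past the threshold without sibling replicate 1 of day 3 (adjusted p = 0.066). prxl2b (−2.06 ± 0.28), the cystatin cst14b.1 (−1.85 ± 0.30), lonrf4 (−1.80 ± 0.14), dhrs12 (−1.79 ± 0.18) and hebp2 (−1.77 ± 0.17) fell as well. Without sibling replicate 2 of day 3, ela2 (3.06 ± 0.67), cpa5 (2.49 ± 0.52) and the immune gene irg1l (−1.88 ± 0.34) lost their calls (adjusted p = 0.13, 0.086 and 0.069). ctrb.1 (2.66 ± 0.82, adjusted p = 0.040) lost its call without any one pool other than mutant replicates 2 and 3 of day 5, with adjusted p up to 0.23, reached without sibling replicate 2 of day 3. Of 11626 probe sets 2129 passed, 958 higher and 1171 lower on day 5. The count was 371 without sibling replicate 2 of day 3, 869 without replicate 1, 1213 without sibling replicate 1 of day 5 and 1416 without replicate 2. It was 3653 with array weights and 265 with sibling replicate 2 of day 3 counted as a mutant.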

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

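The list tests of the difference between the days were chosen after the result was seen, as were the tests of wild-type embryos in a pool, of slower development other than those of the pancreas genes and of all spliceosome genes against day 3 siblings, of a smaller share of eye tissue and of a larger share of dividing cells.

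The mutant effect differed between day 5 and day 3 for 14 of 29 lists, by camera on the difference itself with the preset correlation. Effects lay lower on day 5 for photoreceptors (median difference −1.13), exocrine and endocrine pancreas (−1.05), lens (−0.36), retinal and neural progenitors (−0.33), G2 and mitosis (−0.19), differentiated neurons (−0.18) and liver (−0.14). Smaller shifts of the same sign were found for ribosomal proteins (−0.0776), DNA replication and S phase (−0.0588) and SR and hnRNP splicing regulators (−0.0348). Effects lay higher on day 5 for p53 targets and apoptosis (0.26), the proteasome (0.23), nucleolus and ribosome biogenesis (0.21) and heat shock and unfolded protein response (0.18). With an estimated correlation none of the 14 held (lowest adjusted p = 0.11), and by limma no probe set passed singly, with 772 at an unadjusted p under 0.05.

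Among the control probe sets, which enter no comparison, 2 differed between mutants and siblings. A probe set for the 5′ end of alpha actin was higher in mutants by 0.37 ± 0.12 (adjusted p = 0.047). A control probe set for a zebrafish transcript whose gene was not found in the tables used here differed by −1.59 ± 0.22 (adjusted p = 5.9e-07), with mean signals of 3437 and 1643 on day 3 and 6148 and 1523 on day 5 in siblings and mutants.

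Mutant replicate 3 of day 5 lies nearer to the siblings than the other 2 mutant pools of that day, for example in sart3 (809 against 105 and 132). A share of wild-type embryos would move all genes the same part of the way to the sibling level. The median part of the way was 0.43 for the spliceosome genes called on day 3 and 0.04 for the p53 and apoptosis genes. The difference was 0.387 (33 against 7 genes, two-sided permutation p = 4.7e-04 over genes). The day 3 calls came from a fit that held replicate 3, which disfavours genes on which it departs from its group. sart3 itself missed that call (limma adjusted p = 0.083), and 238 day 3 calls became 400 without replicate 3. Medians near 0 may therefore be too low, so this argues against wild-type embryos only weakly. An earlier collection, as the day 4 in its source name could imply, was not seen in 617 probe sets that change with age without a clear genotype difference. Replicate 3 lay at 0.977 of the distance from day 3 to day 5, against 0.978 and 0.943, so its shortfall from the lower of them was −0.0345. This argues against an earlier collection only weakly. The fit that called the change with age held replicate 3, which disfavours probe sets on which it departs from its group. The lack of a clear day 5 genotype difference was taken from a fit without it. The day 5 end of the distance also holds sibling replicate 2, whose source name says day 4 too. In replicate 3 sart3 itself lay at 0.34 of the way to the sibling level, near the spliceosome genes, while photoreceptor (0.10), pancreas (0.17) and neuronal genes called on day 3 (−0.07) lay nearer to the p53 genes. What also stays open is a pool in which sart3 and the spliceosome transcripts differ less from siblings than other genes do, and no biological explanation of that was tested.

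Photoreceptor and pancreas genes were lower in day 5 mutants. Slower development alone, by less than the time between the 2 sibling days, would leave day 5 mutants between those days. This assumes that levels neither peak nor dip between them, which was not measured. Photoreceptor genes instead had a median of −1.68 relative to the lower of those days (upper quartile −1.19, 25 of 27 genes lower). The 6 that rise in siblings had a median of −1.57 relative to day 3 siblings. For the 12 pancreas genes that rise in siblings that median was −0.544 with an upper quartile of 0.15, so slower growth of the pancreas and a separate loss of its transcripts cannot be told apart, because the genes spread to both sides of 0. A smaller share of the whole eye alone would lower lens genes as much, but photoreceptor genes had a median of −2.33 relative to lens genes (27 against 7 genes, two-sided permutation p = 0.0021 over genes). Lens genes were lower on day 5 themselves (median −0.18, camera adjusted p = 0.011, and 0.27 with an estimated correlation). Only 7 of 49 listed lens genes were measured. The lens genes cannot tell whether the retina alone was smaller or held fewer photoreceptor cells. A loss of photoreceptor transcripts beyond such a delay and a smaller whole eye may remain as a hypothesis, found and tested on the same data. A longer delay was not tested, because no sibling pool was younger than day 3.

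Spliceosome genes were higher in mutants. They lay above day 3 siblings by 0.335 in day 5 mutants, but as only 23 of 83 fell in siblings this does not argue against slower development, which cannot be told apart for the 83 genes (0.311 above the higher sibling day, lower quartile −0.03), for the 23 (0.108 above day 3 siblings, −0.23) or for the PRP19 list (0.116 above the higher sibling day, −0.15), because the genes spread to both sides of 0. A delay shorter than the time between the sibling days would leave day 5 mutants between them if levels neither peak nor dip there, which was not measured. Such a delay is argued against for the Sm and LSm ring (1.07 above the higher day, lower quartile 0.42), the tri-snRNP (1.04, 0.06) and, barely, the U1 and U2 list (0.189, 0.01). A longer delay was not tested. A larger share of dividing cells alone would raise replication and mitosis genes as much, but spliceosome genes lay above those by 0.481 (83 against 81 genes, two-sided permutation p = 1e-05 over genes, the smallest that the permutations can give). Scaling does not account for it, since the shift was 0.51 with median centring and 0.48 after quantile normalization, and no mechanism by which the mutation would raise these genes was tested.

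Regroupings of the arrays within each day tested whether chance groups give results as large. Only the real grouping, 1 of 60, gave as many changed probe sets over both days (1906, highest other 20). Only the real one, 1 of 60, gave as large a spliceosome shift (0.45, highest other 0.39). This makes chance unlikely for both if the arrays of a day are exchangeable, and 1 of 60 is the smallest share possible. The pairing taken for day 5 goes against that condition. Of the 60 splits, 24 part the day 5 pairs. Only the real one, 1 of 24, gave as many probe sets (highest other 20) or as large a shift (highest other 0.38). If the numbers also pair the day 3 arrays, which r does not show, 16 are left, too few for a share under 0.05. For the number of lists called over both days chance cannot be excluded in this way, because 7 of the 60, the real one included, called as many (18, highest other 20). The others of the 7 keep the real grouping of either day 3 or day 5, so they still hold part of the mutant effect. The same is true of the splits with the highest other probe set count (20) and shift (0.39). Splits real on neither day called at most 17 lists, with 0 probe sets over both days and shifts of at most 0.22. The 10 splits of the day 5 arrays are too few for a share under 0.05; 1 of the 10, the real one, gave as many changed probe sets (1690, highest other 0), and 1 of the 10 as many lists (22 when adjusted within that day, highest other 18).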

How the results depend on the processing

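The lists without mutant replicate 3 of day 5 or sibling replicate 2 of day 3, and the lists under other scalings, were added after seeing the data. Results are limited by the number of pools, most of all the 2 per group on day 3, and by low signals without detection calls. No value reversed past its threshold. The spliceosome shift had adjusted p = 0.0501 with an estimated correlation and stayed past its threshold in every other setting run, from 0.40 (pseudocount at 50% of the median) to 0.58 (lower 50% of probe sets left out), with adjusted p from 6.5e-35 to 2.6e-24, and from 0.42 to 0.54 with single arrays left out. Of 136 other values for the counts, this shift and the number of list calls, 110 lay within a factor of 1.5 and 26 did not. With single arrays left out, changed probe sets ranged from 970 to 2289 over both days, 48 to 400 on day 3, 1048 to 2036 on day 5, 0 to 50 for the day difference and 371 to 2377 between the sibling days; a lone day 3 array is assumed to vary like the other groups. List calls were 57 of 87 without mutant replicate 3 of day 5 and 55 without sibling replicate 2 of day 3, the only single arrays left out of the list tests. Array weights gave 505 on day 3, 6 for the day difference and 3653 between the sibling days; the cause was not tested. The day difference had 8 with the pseudocount at 50% of the median, 10 with the replicate block and 26 without the 2 arrays with day 4 source names. Counting sibling replicate 2 of day 3 as a mutant gave 548 over both days, 0 by limma on day 3 (568 at an unadjusted p under 0.05) and 265 between the sibling days, which follows from 1 array moved to the other group. The replicate block changed no other count by over 1.5 times and no list call; among named genes it also ended 7 weak calls of the averaged comparison. With an estimated correlation 13 of 87 list tests passed in place of 56. Over the settings run for each, list values stayed on their side 540 times, lost the call 56 times and gained it 13 times. For named genes these numbers were 2943, 389 and 34. Of 167 named results past the threshold, 90 kept it in every setting run for them. The changes of the filter, the single-day fits and the fit to siblings only were not run for named genes. 15 list values that passed in neither setting changed sign, and no named gene did. On day 3 the median, mean and test differ in sign for ribosomal proteins, heat shock, lens, cartilage and liver, and on day 5 for myeloid cells, none of them past the threshold.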

Other observations

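Genes were named in this part after their values were seen. The list tests below were prompted by ice1 and uspl1 in the first case and by isg15 in the second. They were chosen before the values of the members tested were seen, apart from socs3b in the second. The rule for named genes had already picked socs3b for the day difference.

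Genes that make snRNAs or assemble them into snRNPs stood among the largest rises: ice1 (3.03 ± 0.23), uspl1 (2.43 ± 0.14), ecd (2.03 ± 0.12), which assists assembly of the U5 snRNP, ssb (1.92 ± 0.12), the La protein that binds new RNA polymerase III transcripts, and ruvbl1 (1.80 ± 0.10). It was asked whether this holds for the machinery as a group, which could be the case if these genes move with the spliceosome genes. The 39 measured members not seen before had a median of 0.0488 in the averaged comparison, with 6 up and 2 down (8 and 4 adjusted over the list alone), and camera gave adjusted p = 0.12 (0.12 with an estimated correlation). All 44, the 5 above included, had a median of 0.10 with 11 up and 2 down (adjusted p = 1.0e-03, and 0.012 with an estimated correlation). Single members did rise, with snapc4, a subunit of the snRNA promoter complex, at 1.56 ± 0.17 (an uncertain size, as its sibling means lie under the filter limit), snupn, which imports snRNPs into the nucleus, at 1.09 ± 0.16 and smn1 at 0.54 ± 0.12, while of the Integrator and Gemin genes tested only ints8 passed over both days, lower at −0.51 ± 0.10, and on day 5 ints8 (−0.57) and ints12, higher at 0.48 (adjusted p = 0.0495), passed. Neither test decides, because the first leaves out called genes and the second includes the genes that prompted it.

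isg15, a ubiquitin-like protein induced by interferon, rose by 1.62 ± 0.16 over both days, an uncertain size because its sibling means lie under the filter limit. The 10 other measured interferon and antigen presentation genes, none of which another list holds, had a median of 0.279, with 3 up and none down (4 adjusted over the list alone): b2m (0.87 ± 0.15), socs3b (0.78 ± 0.12) and irf1b (0.53 ± 0.17, adjusted p = 0.048). They stood higher than other genes by camera (adjusted p = 0.018 over the 2 lists tested here), but adjusted p was 0.12 with an estimated correlation. On day 5 their median was 0.55 (adjusted p = 1.4e-03, and 0.096 with an estimated correlation), and on day 3 it was −0.004 (adjusted p = 0.43). An interferon-like response in mutants may be a hypothesis for other samples, resting here on isg15 and 3 of 10 genes that passed, with a median of 0.279 over the 10. Of these, socs3b had already been named for its day difference, and the list was not tested without it.

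The 3′ to 5′ signal ratio of the actin controls was 1.76 to 2.25 on day 3 and 3.90 to 9.24 on day 5, and that of the GAPDH controls was 1.68 to 1.88 and 1.27 to 1.50. On day 5 the actin ratio was 3.90 to 5.99 in mutants and 5.28 to 9.24 in siblings.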
